A study of Sus scrofa with 6 samples.

How the data were processed

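Polyadenylated RNA from the brains of 3 Rongchang pigs and 3 wild boars, 1 library per animal, was measured by RNA sequencing. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was selected on beads, the second cDNA strand was marked with dUTP and removed, and 100-bp paired-end reads were taken on an Illumina HiSeq instrument. Such a library keeps the strand of each transcript. The strand setting used in quantification is not given in the sources used here, so genes that overlap an antisense partner are uncertain. The tools named are TopHat2 2.0.11, Cufflinks 2.2.1 and Cuffdiff, per the submitters' processing notes, without a stated role or order for each. The genome build and annotation release are not given in the sources used here, so no coordinates are printed.

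The deposited table holds 1 FPKM value (fragments per kilobase of transcript, scaled to the fragments mapped) per gene and library, for 18225 Ensembl gene identifiers. Its header names the libraries and no unit. The unit was judged from the named tools and from the values, which are decimals with exact zeros and sum to 568921 to 687359 per library. Scaling across libraries by the authors is not stated. FPKM values carry no read counts, and depth per library is therefore unknown. Low values were examined for a shared step between libraries. Among values under 0.15 FPKM, at most 23.5% of the ratios between any pair of libraries fell in 1 window of 0.04 log2 units, so relative depth was not recovered. No interval based on depth is given. Reads from near-identical copies, such as genes of the major histocompatibility complex or ribosomal protein genes and their pseudogenes, can be split among them in ways these values do not show.

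Symbols were taken from a table pairing Ensembl identifiers with names. A symbol was found for 10937 of 18225 identifiers (60.0%) and for 8538 of the 13152 genes tested (64.9%). A gene in a list that has no matched symbol was not analysed here, and a symbol on several identifiers was taken from the one with the highest mean.

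Groups follow the breed in the labels. Wild boar was compared with Rongchang using limma 3.58.1 in R 4.3.3, on log2(FPKM + 1) of the deposited values, for genes with at least 1 FPKM in at least 3 of the 6 libraries. The test was two-sided with a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are wild boar minus Rongchang on the log2(FPKM + 1) scale, which understates changes of genes with low values. The labels number the animals but say nothing more of their origin, so p-values measure the spread between these libraries.

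Before the data were examined, 42 gene lists were fixed in 6 classes (immune, cell type, brain region, neural function, metabolism and sample quality). The 34 lists with at least 5 genes tested entered limma's camera, a competitive test of a list against all other genes, with a preset correlation of 0.01 between genes. Adjustment ran over all 34 lists. The same lists were tested with the correlation estimated from the data, and with fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. Single members were also adjusted over the list alone, with no correction for the number of lists.

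The genes named were to be the 12 with the largest rise and the 12 with the largest fall among genes with a symbol, past the threshold, with the breeds fully apart and a mean of at least 2 FPKM in the higher breed. Where too few passed, each direction was filled to 5 with the smallest unadjusted p. Up to 4 members with the smallest p were named per list described, along with the most abundant member where cell type or region makeup is described. The rule names no gene without a symbol. The 4 identifiers named in the text fall outside it and were chosen after their values were seen.

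The animals of both breeds are numbered 1 to 3. The deviations of same-numbered libraries from their breed means correlated at 0.28, 0.59 and 0.37, all above the bound of 0.1 set for pairing, while pairs with different numbers lay between −0.45 and 0.12. The numbers were therefore taken to pair the libraries, from the data alone, since nothing in the labels says what a number marks. Rongchang 1 with wild boar 3, at 0.12, also lay above that bound. By Spearman correlation over the genes tested, wild boar 3 lay nearer to Rongchang 1 (0.964) than to Rongchang 3 (0.961). The pairing, and the counts with the block that rest on it, are therefore uncertain. The comparison without the pairing remained the primary one, as fixed before the data were examined, and the fit with the number as a block is given where it changed a call or a count.

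The procedure was checked on 20 simulated tables of 13152 genes with 200 changed genes and 3 libraries per breed. It recovered 48.5% of 2-fold changes and 89.9% of 4-fold changes, with 5.9 false calls per table on average. These are changes on the log scale of the fit, on which a gene with a low value needs a larger change in FPKM. Recovery of 2-fold and 4-fold changes in FPKM was not tested, and would be lower for genes with low values. No unchanged list was called on average in those tables (0), and a list shifted by −0.25 was called in 100% of them. The simulated noise was independent between genes, which real lists are not.

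Alternatives were other pseudocounts (0.1 and 0.01), no filter or a mean of at least 5 FPKM, quantile normalization, median and upper-quartile scaling, no variance trend, robust moderation, library weights, a 2-fold minimum, the block, the other list tests and leaving out each library. After the data were examined, 5 more were added: median scaling with the block, mitochondrially encoded genes left out with totals equalised, both libraries numbered 2 left out, and the block with an estimated correlation or fry. Methods for read counts were not run on FPKM. Figures were drawn with matplotlib 3.10.9.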

Results

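Messenger RNA was measured in the brains of 3 wild boars and 3 Rongchang pigs, a domesticated Chinese breed, all 210 days old. The labels name the tissue as brain and give no region. The title of the series poses a difference in immune response between the domesticated and the wild animals as its question. Values are deposited FPKM given as mean ± SD with n = 3 per breed, and fold changes are wild boar minus Rongchang in log2(FPKM + 1). The table lists 18225 genes, of which 16510 to 17090 had a value above 0 in each library. Genes of neurons and astrocytes were abundant in both breeds. The synaptic vesicle fusion gene SNAP25 stood at 988 ± 187 FPKM in Rongchang and 980 ± 170 in wild boar (log2 fold change −0.01). The astrocyte-rich secreted chaperone CLU stood at 1513 ± 247 and 1507 ± 419 (−0.04). Mitochondrially encoded messenger RNAs made up 38.4% ± 7.71 of all FPKM in Rongchang and 43.8% ± 2.92 in wild boar (exact permutation test, two-sided, p = 0.4; the smallest p that 3 against 3 animals allow is 0.1). Sequencing depth is unknown for FPKM values. On the first principal component the libraries numbered 2 of both breeds stood apart from the other 4, and on the second all wild boars lay above all Rongchang pigs.

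**Figure D1:**
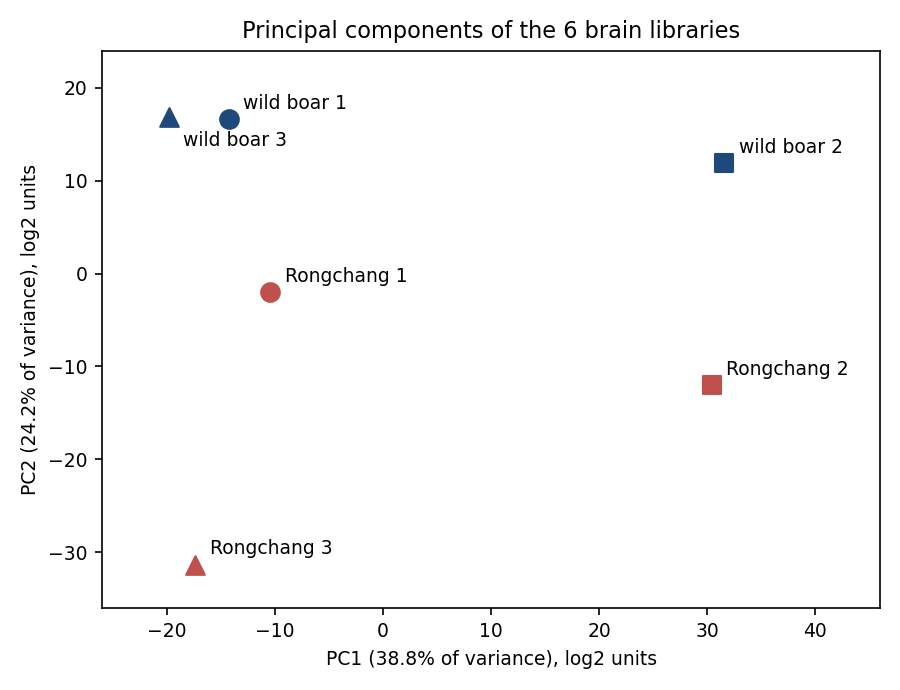
Principal components of log2(FPKM + 1) over the genes tested, with PC1 on the x axis (38.8% of variance) and PC2 on the y axis (24.2%). Each point is 1 library, red for Rongchang and blue for wild boar, with a circle, square or triangle for animal 1, 2 or 3. The libraries numbered 2 sit at 30.5 and 31.6 on PC1, and the other 4 sit between −19.8 and −10.5.

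Of 13152 genes tested between the breeds, 1 was lower in wild boar and 0 were higher (limma, adjusted p). The lower gene, ENSSSCG00000008843, has no symbol, and was at 4.54, 5.86 and 5.16 FPKM in the Rongchang libraries and listed at 0 in all 3 wild boars (log2 fold change −2.62, adjusted p = 0.00123). It fell outside the naming rule and was chosen after its values were seen. At an unadjusted p under 0.05, 789 genes stood apart, 76 higher and 713 lower in wild boar, where evenly spread p-values would give 658. That mark takes the libraries as independent, which the pairing by number puts in doubt. With the animal number as a block the calls were the same in number, 0 higher and 1 lower, and 2289 genes had an unadjusted p under 0.05 (185 higher and 2104 lower), against 1379 (719 and 660) after median scaling with the block. Evenly spread p-values would give 658 with the block too. The median gene was lower in wild boar by −0.13 log2 units, and 77.9% of genes lay below 0. After scaling each library to the same median, the median fold change was 0.02, and the genes with an unadjusted p under 0.05 split into 248 higher and 246 lower. Fold changes of gene lists are therefore given also relative to the median gene. Those of single genes are not, and include this shift.

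No gene with a symbol passed the threshold, and of the 5 with the smallest unadjusted p in each direction, 4 lower and 5 higher are given as values and 1 lower is not used here. NECTIN1, a cell adhesion molecule and entry receptor for alphaherpesviruses, was at 2.23, 2.63 and 2.53 FPKM in Rongchang and at 0.42, 0 and 0 in wild boar (log2 fold change −1.62, adjusted p = 0.112). It passed when wild boar 1 was left out (adjusted p = 0.0332). The fibroblast growth factor carrier FGFBP3 stood at 3.12 ± 1.23 FPKM in Rongchang and 0.76 ± 0.185 in wild boar (log2 fold change −1.19). The LIM-domain regulator LMO1 stood at 5.51 ± 0.339 and 2.96 ± 0.374 (−0.72), and CTH, the enzyme that makes cysteine from cystathionine, at 2.98 ± 0.311 and 1.46 ± 0.0443 (−0.69). In the other direction, HHIPL2 stood at 1.30 ± 0.437 FPKM in Rongchang and 3.23 ± 0.638 in wild boar (0.88). CNMD, which encodes an inhibitor of vessel growth, stood at 1.09 ± 0.45 and 2.56 ± 0.492 (0.78), and LARP7, a binding protein of the 7SK RNA, at 4.98 ± 0.213 and 8.73 ± 0.986 (0.70). The enkephalin precursor PENK was at 7.43 ± 1.74 and 12.6 ± 2.57 (0.69), and the neurotrophin BDNF at 3.94 ± 0.208 and 6.11 ± 0.728 (0.52). Adjusted p for these 8 genes other than NECTIN1 ranged from 0.555 to 0.766.

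The immune question was addressed with 9 lists. Type I interferon-stimulated genes were lower in wild boar than other genes in camera (adjusted p = 0.00368), but not with an estimated correlation (adjusted p = 0.715 with an estimated correlation) or in fry (adjusted p = 0.485). Of the list, 24 of the 25 tested had a fold change below 0, with a median of −0.38, or −0.25 relative to the median gene. USP18, which removes the ubiquitin-like modifier ISG15 from proteins, stood at 3.44 ± 1.52 FPKM in Rongchang and 1.5 ± 0.226 in wild boar (log2 fold change −0.76). IRF7, a transcription factor of the interferon response, stood at 4.33 ± 1.44 and 2.38 ± 0.565 (−0.63), the mitochondrial nucleotide kinase CMPK2 at 4.97 ± 0.782 and 3.29 ± 0.386 (−0.47), and the antiviral gene IFIT2 at 4.23 ± 0.110 and 3.0 ± 0.412 (−0.39). None of the 25 members passed, over all genes or adjusted over the list alone (0 in limma), and 6 had an unadjusted p under 0.05, all lower. The camera call ended without Rongchang 1 (adjusted p = 0.386, median −0.03 relative to all genes) and with a minimum mean of 5 FPKM (adjusted p = 0.149), within a range of 5.96e-09 to 0.783 over 24 alternatives.

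The other 8 immune lists did not pass in camera, with adjusted p from 0.146 to 0.952. In the class II antigen presentation list, 7 of 8 members lay below 0, of which 6 lay below the median gene. HLA-DRA, the alpha chain of the DR molecule, stood at 52.9 ± 43.0 FPKM in Rongchang and 24.3 ± 11.3 in wild boar (log2 fold change −0.90), and SLA-DQB1 at 16.0 ± 9.79 and 7.76 ± 5.38 (−0.98). The lysosomal proteases LGMN (10.3 ± 1.34 and 8.01 ± 1.28) and CTSH (2.42 ± 0.80 and 1.67 ± 0.308) had fold changes of −0.33 and −0.34. The list's adjusted p was 0.331, and 0.00486 without Rongchang 2 and 0.0135 without wild boar 1. With all libraries and an estimated correlation, camera gave it an adjusted p of 0.888. All 8 class I presentation genes lay below 0, but 2 lay above the median gene and the median relative to it was −0.05 (adjusted p = 0.495), among them the peptide-trimming enzyme ERAP1 (3.35 ± 0.432 and 2.35 ± 0.444, −0.38) and the peptide-loading chaperone TAPBP (12.9 ± 0.385 and 11 ± 1.5, −0.22). Of 5 T and NK cell markers tested, 4 lay below 0, near the 77.9% of all genes that did, and the same 4 lay below the median gene (adjusted p = 0.182). CD8A, the co-receptor of cytotoxic T cells, was lower at 1.06 ± 0.0556 FPKM in Rongchang and 0.463 ± 0.0386 in wild boar, with a log2 fold change of −0.49, and was the 1 member that fell when adjusted over the list alone (adjusted p = 0.0365; 0.766 over all genes). That call was lost with the block (0 members), and fry with the block passed the list (adjusted p = 0.0317), which camera did not with the block (0.469), nor with the block and an estimated correlation (0.783). The T cell adaptor SKAP1 stood at 1.33 ± 0.0575 and 0.876 ± 0.164 (−0.32).

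Among cytokines and their receptors, 21 of 27 genes lay below 0 but 16 lay above the median gene, and the list did not pass (adjusted p = 0.707). TNFSF13B, the B-cell survival factor BAFF, stood at 2.86 ± 0.634 FPKM in Rongchang and 1.09 ± 0.503 in wild boar (log2 fold change −0.90, adjusted p = 0.724, and 0.0931 adjusted over the list alone). IL18 stood at 9.33 ± 2.63 and 5.07 ± 2.2 (−0.80), and TGFB2 at 129 ± 63.5 and 67.9 ± 6.01 (−0.79). With the block, 2 members of the list fell when adjusted over the list alone, where 0 did without it in limma and 2 had an unadjusted p under 0.05. The monocyte attractant CCL2 stood at 2.16 ± 0.732 and 1.10 ± 0.550 (−0.60) and the CXCL12-scavenging receptor ACKR3 at 6.69 ± 2.62 and 4.42 ± 0.539 (−0.45), in a chemokine list with adjusted p = 0.952. In the Toll-like receptor and NF-kappaB list (adjusted p = 0.204) the kinases MAP3K7 (3.70 ± 0.263 and 2.42 ± 0.391, −0.46) and CHUK (12.1 ± 0.311 and 9.06 ± 0.990, −0.39) had the smallest p. In the complement list (adjusted p = 0.146) the alternative pathway genes CFD (13.6 ± 9.59 and 6.95 ± 2.48, −0.74) and CFB (4.03 ± 0.675 and 5.22 ± 1.17, 0.30) lay in opposite directions. The iron-carrier scavenger LCN2 (18.4 ± 4.07 and 12.6 ± 3.42, −0.52) and the pentraxin PTX3 (2.64 ± 0.985 and 1.71 ± 0.138, −0.39) led the acute-phase list (adjusted p = 0.300). The complement, cytokine and Toll-like receptor lists had medians and means below 0 (medians −0.04, −0.07 and −0.07) but tested as higher than other genes. The median gene lay at −0.13, below those medians, though the cytokine list's mean of −0.15 lay lower still. The acute-phase list also tested as higher, with a median of 0.01 and a mean of −0.04. Without wild boar 2 the complement list passed (adjusted p = 0.00641) and the Toll-like receptor list did (adjusted p = 0.0499). Without Rongchang 3 the complement list passed as well (adjusted p = 0.0337), and without Rongchang 2 the chemokine list did (adjusted p = 0.0295). With all libraries and an estimated correlation, camera passed none of them. Adjusted p was then 0.784 for the complement list, 0.784 for the Toll-like receptor list and 0.979 for the chemokine list.

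**Figure D2:**
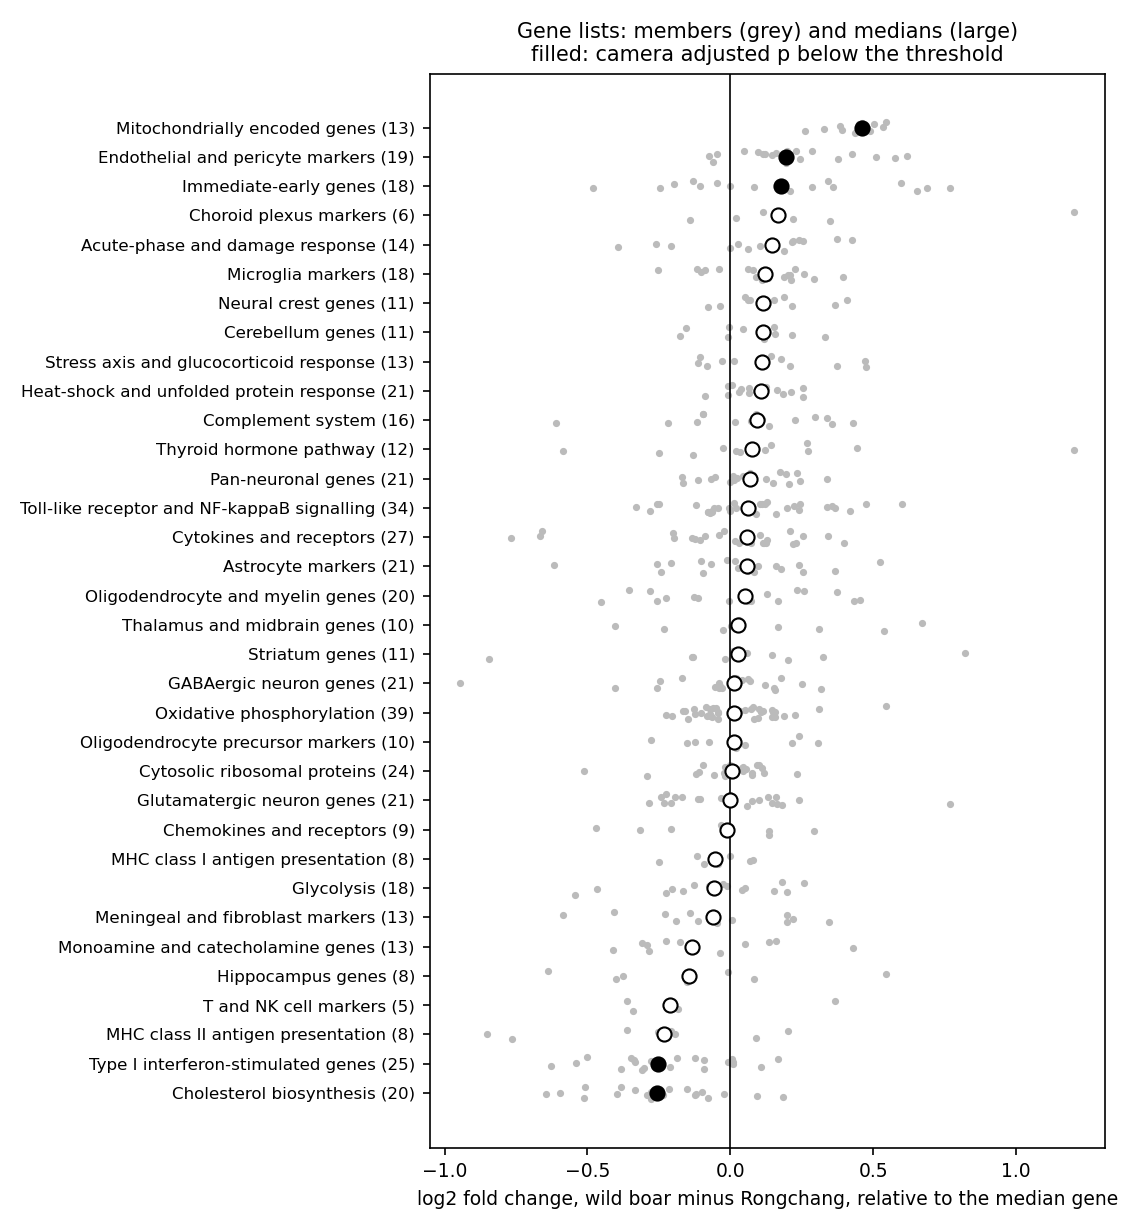
Gene lists tested between the breeds, with the number of genes tested in parentheses. The x axis gives the log2 fold change, wild boar minus Rongchang, relative to the median gene; grey points are genes, large circles list medians, filled where camera's adjusted p was under 0.05. The 5 filled lists have medians of −0.26 for cholesterol biosynthesis, −0.25 for interferon-stimulated genes, 0.18 for immediate-early genes, 0.19 for endothelial and pericyte markers and 0.46 for mitochondrially encoded genes, and 0 of the 34 lists passed with an estimated correlation or in fry.

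Genes of cholesterol biosynthesis were lower in wild boar than other genes in camera (adjusted p = 1.8e-04), which was not kept with an estimated correlation (adjusted p = 0.619 with an estimated correlation) or in fry (adjusted p = 0.204). Of 20 tested, 19 had a fold change below 0, with a median of −0.39, or −0.26 relative to the median gene. DHCR7, which catalyses the last step to cholesterol, stood at 8.57 ± 0.544 FPKM in Rongchang and 4.82 ± 0.875 in wild boar (log2 fold change −0.73), and LSS, which closes the sterol ring, at 22.7 ± 2.98 and 14.2 ± 1.80 (−0.64). Both fell when adjusted over the list alone (adjusted p = 0.0370 and 0.0471), and neither passed over all genes (0.724 and 0.737). The sterol reductase TM7SF2 (49.5 ± 8.58 and 31.4 ± 6.58, −0.64) and the sterol dehydrogenase NSDHL (16.2 ± 1.90 and 11.1 ± 1.86, −0.52) showed no overlap between the breeds. Of all genes tested, 1648 (12.5%) showed no overlap, where 3 against 3 libraries give 10% by chance. Over 24 alternatives the adjusted p of the cholesterol list ran from 2.79e-06 to 0.771 and was under 0.05 in 20. With the block, 12 members fell when adjusted over the list alone.

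All 13 mitochondrially encoded genes tested lay above 0, with a median of 0.33, or 0.46 relative to the median gene, and the list was higher in wild boar in camera (adjusted p = 4.48e-06; adjusted p = 0.619 with an estimated correlation). The complex I subunit ND2 stood at 5061 ± 1569 FPKM in Rongchang and 6519 ± 1061 in wild boar (log2 fold change 0.40), and CYTB of complex III at 8234 ± 1816 and 10575 ± 1631 (0.37). None of the 13 passed by itself (0 in limma, 0 at an unadjusted p under 0.05), and quantile normalization ended the list's call (adjusted p = 0.652), within a range of 1.08e-11 to 0.779. The 13 genes made up 30.0% to 46.8% of FPKM per library and so hold top ranks. Quantile normalization gives each rank the same value in every library and removes most of a difference that such genes share. The call lost there therefore says little about them. The 39 genes of oxidative phosphorylation encoded in the nucleus had a median of 0.01 relative to the median gene (adjusted p = 0.357), with UQCRC2 of complex III at 30.4 ± 1.30 and 24 ± 3.29 (−0.34). That list passed as higher without Rongchang 3 (adjusted p = 0.000101) or wild boar 2 (0.000302) or with library weights (0.0163), and as lower without Rongchang 2 (0.00960), but not with an estimated correlation (0.888). The glycolysis list did not pass (18 tested, adjusted p = 0.495). Its member PFKL, the liver-type phosphofructokinase, stood at 20.7 ± 1.98 and 13.3 ± 0.190 (−0.60), and the lactate exporter SLC16A3 at 2.96 ± 1.41 and 1.37 ± 0.0530 (−0.68). With the block 1 glycolysis gene fell when adjusted over the list alone.

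**Figure D3:**
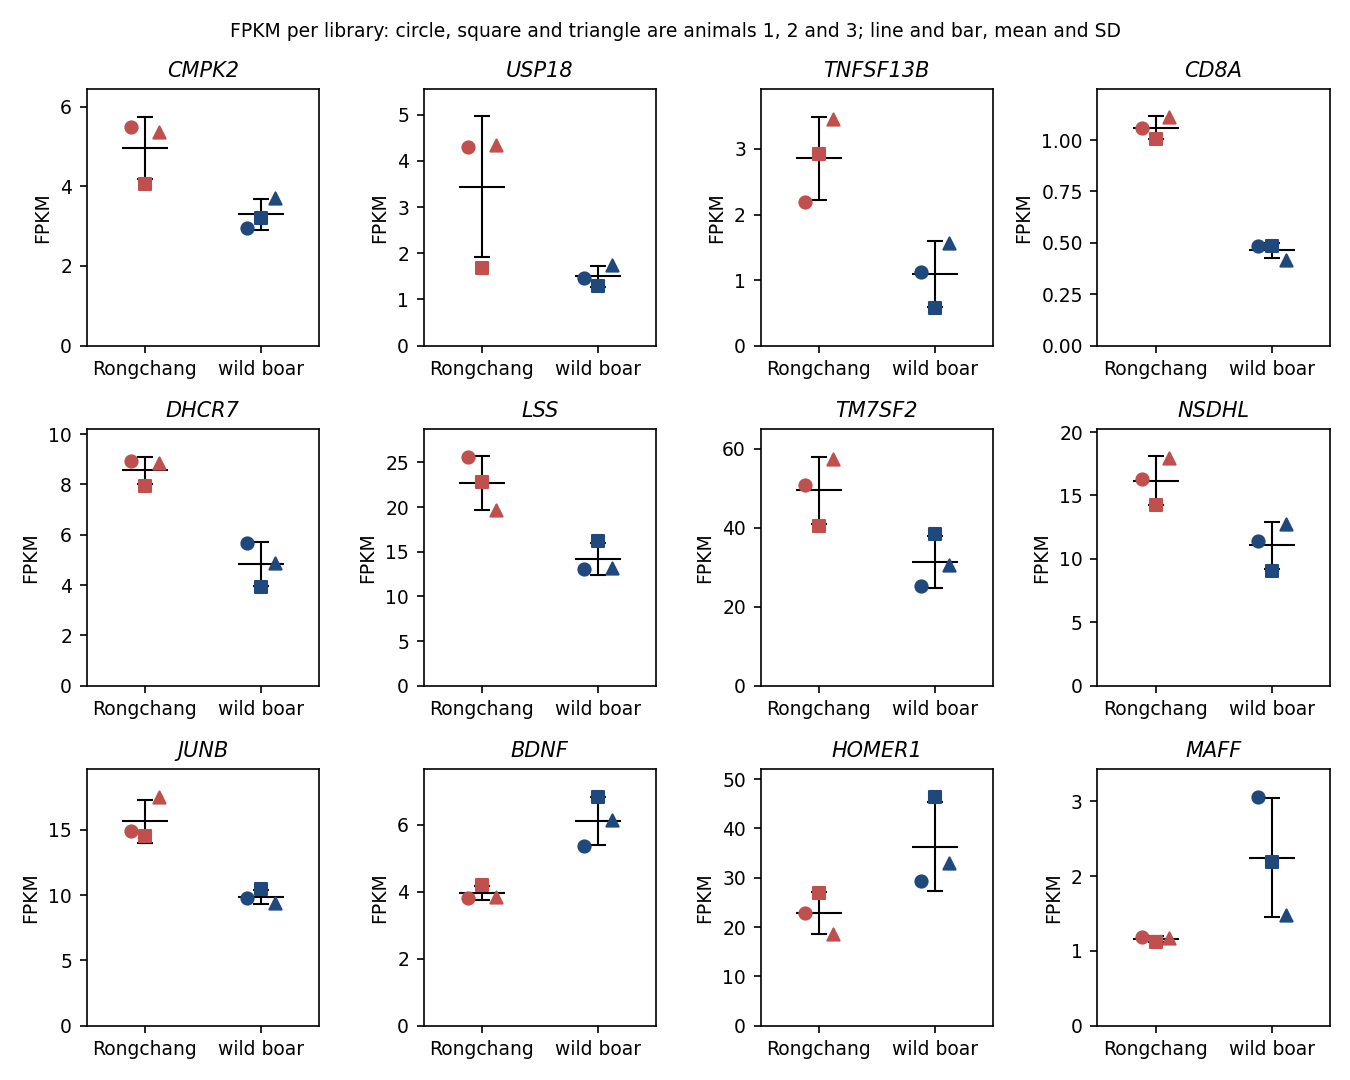
FPKM of 12 named genes (y axis, linear from 0) in each library of Rongchang (red) and wild boar (blue), with a circle, square or triangle for animal 1, 2 or 3, a horizontal line at the mean and bars of 1 SD. The top panels hold immune genes, the middle panels cholesterol biosynthesis and the bottom panels immediate-early genes. CD8A ranges around 1.06 in Rongchang and 0.463 in wild boar, while USP18 of Rongchang 2 lies with the wild boars.

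The brain region is not stated, so 14 lists of cell type and region markers were compared. Markers of endothelial cells and pericytes were higher in wild boar relative to other genes in camera (adjusted p = 1.8e-04), but not with an estimated correlation (adjusted p = 0.619 with an estimated correlation) or in fry (0.911). Of 19 tested, 16 lay above the median gene, with a median of 0.06, or 0.19 relative to it. The pericyte receptor PDGFRB stood at 3.48 ± 0.341 FPKM in Rongchang and 5.43 ± 1.87 in wild boar (log2 fold change 0.49), the endothelial adhesion molecule PECAM1 at 7.09 ± 1.69 and 9.53 ± 2.16 (0.38), ENG at 7.59 ± 3.66 and 10.1 ± 1.42 (0.44) and TIE1 at 6.56 ± 0.269 and 8.41 ± 2.03 (0.29). The most abundant member, the thyroid hormone transporter SLCO1C1, stood at 27.4 ± 10.2 and 27.7 ± 11.8 (−0.01). No member passed (0 in limma, 0 at an unadjusted p under 0.05). Adjusted p of the list ran from 7.03e-09 to 0.911 over 24 alternatives.

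The other 13 cell type and region lists did not pass in camera, with adjusted p from 0.114 to 0.834. Microglia markers had a median of 0.12 relative to the median gene (18 tested, adjusted p = 0.114), with the leukocyte phosphatase PTPRC at 2.90 ± 0.362 and 2.34 ± 0.216 (log2 fold change −0.22), the lysosomal marker CD68 at 3.55 ± 1.34 and 4.32 ± 0.204 (0.26), and the most abundant member C1QA at 32.2 ± 13.4 and 27.3 ± 11.3 (−0.25). The microglia list passed as higher without Rongchang 1 (adjusted p = 0.0118), Rongchang 3 (0.0415) or wild boar 2 (4.01e-06), with library weights (0.0181) and with both libraries numbered 2 left out (5.74e-04), within a range up to 0.949, but not with an estimated correlation (0.871). Among astrocyte genes, of which 13 of 21 lay above the median gene, the folate enzyme ALDH1L1 stood at 7.38 ± 0.520 and 4.10 ± 1.41 (log2 fold change −0.75) and CHRDL1 at 25.2 ± 0.369 and 19.2 ± 1.91 (−0.38). Among oligodendrocyte genes, of which 12 of 20 lay above the median gene, TSPAN2 stood at 6.23 ± 1.86 and 3.74 ± 0.662 (−0.59) and the myelin enzyme CNP at 157 ± 17.6 and 119 ± 23.3 (−0.42). Of 8 hippocampal genes tested 7 lay below 0, of which 6 lay below the median gene (adjusted p = 0.188). C1QL2, a secreted synaptic protein, stood at 6.12 ± 0.299 and 3.26 ± 1.09 (log2 fold change −0.77) and fell when adjusted over the list alone (adjusted p = 0.0312; 0.724 over all genes). MAN1A1 stood at 4.26 ± 0.690 and 2.71 ± 0.624 (−0.51), and the most abundant member FAM163B at 43.3 ± 1.92 and 35.5 ± 3.44 (−0.28). With the block, 4 of the 8 fell when adjusted over the list alone, and the list passed in fry (adjusted p = 0.04), which tests against 0, but not in camera (0.257) or with an estimated correlation (0.772).

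Immediate-early genes, which neurons transcribe within minutes of activity, were higher in wild boar relative to other genes in camera (adjusted p = 0.00475), but not with an estimated correlation (adjusted p = 0.619 with an estimated correlation) or in fry (0.911), and their members went both ways. Of 18 tested, 10 lay above 0 and 8 below, with a median of 0.04, or 0.18 relative to the median gene. BDNF, given above, the synaptic scaffold HOMER1 (22.8 ± 4.19 and 36.3 ± 8.98 FPKM, log2 fold change 0.64) and the small Maf factor MAFF (1.16 ± 0.0370 and 2.24 ± 0.795, 0.56) lay higher. The AP-1 subunit JUNB had the smallest p in the list and lay the opposite way, at 15.7 ± 1.66 in Rongchang and 9.86 ± 0.546 in wild boar (−0.61; adjusted p = 0.0505 over the list alone and 0.724 over all genes). Adjusted p of the list ran from 0.000299 to 0.911 over 24 alternatives. The camera call ended without wild boar 2 (adjusted p = 0.143), with no filter (0.129), with library weights (0.193), with both libraries numbered 2 left out (0.210) and with median scaling and the block (0.0504). Adjusted over the list alone, no member passed in limma (0, with 5 at an unadjusted p under 0.05, 4 higher and 1 lower), whereas with the block 3 rose and 1 fell.

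Genes of the stress axis and glucocorticoid response did not pass (13 tested, median 0.11 relative to the median gene, adjusted p = 0.114), and did with the block (adjusted p = 0.0338), but not with the block and an estimated correlation (0.771) or in fry with the block (0.773). The glucocorticoid-induced kinase SGK1 stood at 18.8 ± 2.09 FPKM in Rongchang and 24 ± 1.36 in wild boar (log2 fold change 0.34), and the glucocorticoid receptor NR3C1 at 6.13 ± 1.06 and 5.04 ± 0.916 (−0.24). The stress list also passed without Rongchang 3 (adjusted p = 0.0280) or wild boar 1 (0.0128), with a mean of at least 5 FPKM (0.0243), with library weights (0.0442) and with median scaling and the block (0.0198), within a range up to 0.949. Of 13 monoamine genes tested 10 lay below 0, near the 77.9% of all genes that did, and 9 lay below the median gene (adjusted p = 0.188). Among them, the serotonin receptor HTR2C stood at 4.38 ± 0.472 and 2.71 ± 0.525 (−0.54) and the decarboxylase DDC at 4.01 ± 1.16 and 2.69 ± 0.523 (−0.43). Across all 42 lists, 545 distinct members were tested and 0 passed in limma, with 40 at an unadjusted p under 0.05, of which 6 were higher and 34 lower in wild boar. The 13152 genes tested leaned the same way, with 789 at an unadjusted p under 0.05, 76 higher and 713 lower. With an estimated correlation 0 of the 34 lists passed, 0 did in fry, and 0 had an unadjusted p under 0.05 with an estimated correlation. For the lists camera passed, the mean log2 deviation of each library was compared. Without scaling, an exact permutation test gave p = 0.1, the smallest possible, for cholesterol and 0.3 for interferon-stimulated genes. The exact permutation test gave p = 0.3 for mitochondrially encoded, 0.6 for endothelial and 0.8 for immediate-early genes. After median scaling, the exact permutation test gave these lists p = 0.2 to 0.4, with 0.3 for cholesterol. Without scaling, the exact permutation test also gave p = 0.1 for the T and NK cell, hippocampal, monoamine and glycolysis lists. Camera passed none of those. After median scaling, the exact permutation test still gave p = 0.1 for the T and NK cell and monoamine lists. The lists camera passed had estimated correlations of 0.11 to 0.60, against the preset 0.01.

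**Figure D4:**
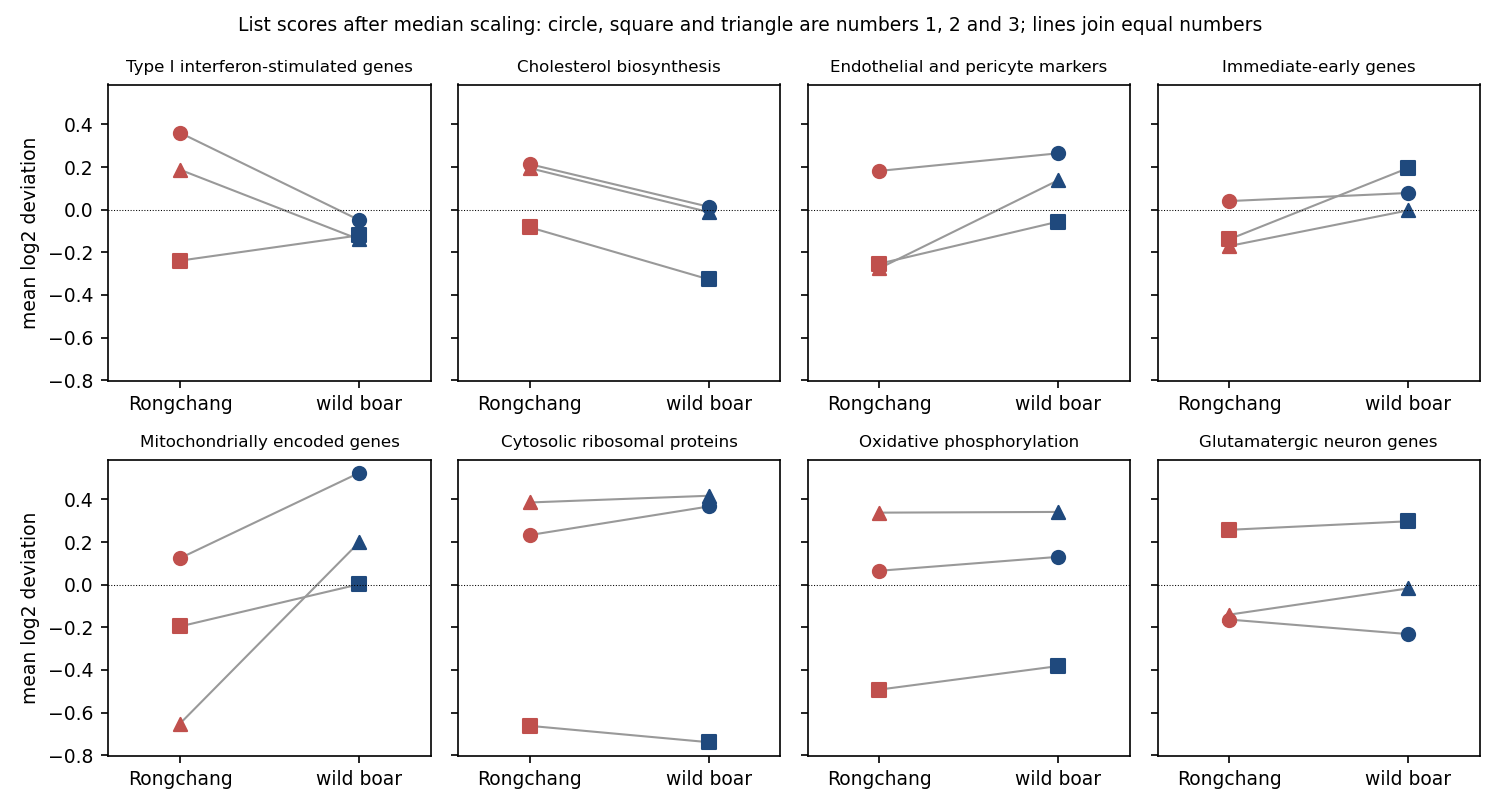
Mean log2 deviation of a list's genes from their mean over the 6 libraries, after median scaling (y axis), for Rongchang (red) and wild boar (blue), with lines joining libraries of equal number. Ribosomal protein scores of the libraries numbered 2 are −0.66 and −0.74, far below the other 4. Cholesterol scores are lower in wild boar in each of the 3 pairs, and interferon scores in 2 of 3. Mitochondrially encoded, endothelial and immediate-early scores are higher in each of the 3 pairs, as are those of oxidative phosphorylation, which camera did not pass.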

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

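The settings with both libraries numbered 2 left out, the mitochondrially encoded genes left out, and the block combined with median scaling, an estimated correlation or fry were chosen after the data were seen. Groups of 3, unknown depth and values near 0 limit these results; the cause of a change was not tested unless the setting itself shows it. Of 1435 values of the 71 named genes under alternatives, 1405 kept their direction and their side of the threshold, 1 lost the call, 1 gained it and 28 took the opposite direction. Of 446 values of the 19 lists with printed results, 362 kept both, 28 lost the call, 22 gained it and 34 took the opposite direction. For single genes, dropping the variance trend, robust moderation, the block and the 2-fold minimum leave fold changes as they were, so no direction could change there. Median scaling with the block repeats the fold changes of median scaling. Only ENSSSCG00000008843 was called in the primary fit, and a gene that missed the filter of a setting gave no value.

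Counts of genes. The single gene called became 3 with a pseudocount of 0.1 (limma, 785 genes at an unadjusted p under 0.05), 2 with 0.01 (788), 0 with a mean of at least 5 FPKM (405; the filter removes ENSSSCG00000008843) and 0 with both libraries numbered 2 left out (1131; without Rongchang 2 that gene no longer met the filter). With a pseudocount of 0.01 ENSSSCG00000008843 was not called (adjusted p = 0.44, within 0.000538 to 0.44 over its alternatives). Leaving out 1 library gave 0 (Rongchang 3, 570 genes at an unadjusted p under 0.05) to 4 genes (wild boar 1), and without any 1 Rongchang library ENSSSCG00000008843 no longer met the filter. The replicate block also called 1 gene, the same one. Calls among list members stayed at 0 in limma under each alternative, with 40 at an unadjusted p under 0.05 in the primary fit.

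Counts of lists. Immune lists went from 1 to 0 with a mean of at least 5 FPKM, with an estimated correlation, in fry, and with an estimated correlation and the block, and from 0 (without Rongchang 1) to 3 (without Rongchang 2 or wild boar 2) when 1 library was left out. Cell type and region lists went from 1 to 2 with no filter, with library weights and with median scaling and the block, to 4 with both libraries numbered 2 left out, and to 0 with an estimated correlation, in fry, and with an estimated correlation and the block; leaving out 1 library gave 1 (wild boar 3) to 4 (wild boar 1 or 2). The other lists went from 3 to 6 with library weights, and to 0 with an estimated correlation, in fry, and in both of these with the block; leaving out 1 library gave 4 (Rongchang 1) to 7 (Rongchang 3). Among lists whose calls are not given beside the results, the heat-shock and unfolded protein list (adjusted p = 0.137) passed as higher in 6 of 24 alternatives, among them median scaling (0.0396), within 0.00112 to 0.911. The ribosomal protein list (adjusted p = 0.357) passed in 4, as higher in 3 and as lower without Rongchang 2 (0.0154), within 7.28e-06 to 0.932. Astrocyte, glutamatergic, neuronal, oligodendrocyte, meningeal, thalamic and neural crest lists passed in 1 to 3 alternatives each, and a macrophage list with too few genes otherwise passed with no filter. Apart from the calls given beside the results, the block changed no other camera call. Adjusted over the list alone, it also called members of 4 further lists in which limma called 0 without it: 5 oligodendrocyte genes (1 at an unadjusted p under 0.05 without it), 1 glutamatergic gene (1), 2 striatal genes (2) and the 1 neutrophil gene tested (0).

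Directions of genes (log2 fold change). SLCO1C1 turned to 0.13 with quantile normalization, 0.16 with median scaling and with median scaling and the block, 0.14 with upper-quartile scaling, 0.014 with mitochondrial genes left out and 0.23 without the libraries numbered 2. SNAP25 turned to 0.14 (quantile), 0.17 (median, with and without the block), 0.15 (upper quartile), 0.13 (library weights) and 0.020 (mitochondrial genes left out). CLU turned to 0.14 (median, with and without the block), 0.12 (upper quartile), 0.083 (library weights) and 0.080 (without the libraries numbered 2). C1QA turned to 0.0052 (library weights). Leaving out 1 library gave −0.31 to 0.31 for SLCO1C1, −0.16 to 0.14 for SNAP25, −0.18 to 0.22 for CLU and −0.55 to 0.15 for C1QA. Leaving out 1 library took others below 0.5 of their value without a change of direction: HLA-DRA to −0.28, CTSH to −0.17, ACKR3 to −0.22, PTX3 to −0.18 and ND2 to 0.14 without Rongchang 3, CFD to −0.24 and CD68 to 0.086 without Rongchang 1, SLA-DQB1 to −0.46 and TIE1 to 0.14 without wild boar 2, and NR3C1 to −0.12 without wild boar 3. Others shrank by a factor of more than 1.5: TGFB2 to −0.44 without Rongchang 2, CYTB to 0.23, ENG to 0.26 and SLC16A3 to −0.41 without Rongchang 3, DDC to −0.24 and TTR to 0.69 without Rongchang 1, CFB to 0.15 without wild boar 1, PDGFRB to 0.26, IL18 to −0.52, LCN2 to −0.32 and LGMN to −0.21 without wild boar 2, and CCL2 to −0.37 and TAPBP to −0.12 without wild boar 3. Median scaling moved some lower genes toward 0: TAPBP to −0.065, FAM163B to −0.11, NR3C1 to −0.094 and PTPRC to −0.095. It moved some higher genes away from 0, among them LARP7 and PENK, both to 0.85. KIT came as near to 0 as −0.065 over its alternatives.

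Directions of lists (median relative to all genes). The chemokine list tested the other way at −0.0036 (pseudocount 0.1), −0.0038 (0.01), 0.054 (no filter) and −0.0081 (mean of at least 5 FPKM), and the cytokine list at −0.020 (mean of at least 5 FPKM). The oxidative phosphorylation list did so at 0.013 with the replicate block, alone or with an estimated correlation, and at −0.028 without the libraries numbered 2. In fry, which measures direction from 0 and not from other genes, the opposite direction came, with and without the block, for the complement (0.094), cytokine (0.059), Toll-like receptor (0.061), acute-phase (0.14), microglia (0.12) and oxidative phosphorylation (0.013) lists, and without the block for the stress axis (0.11). Leaving out 1 library gave −0.12 to 0.11 for class I presentation, −0.45 to −0.064 for class II, −0.027 to 0.21 for complement, −0.28 to 0.13 for chemokines, −0.050 to 0.12 for cytokines, −0.10 to 0.35 for microglia and −0.21 to 0.20 for oxidative phosphorylation. For lists that kept their direction it gave 0.074 (wild boar 1) to 0.36 (Rongchang 1) for endothelial and pericyte markers, −0.35 to −0.13 (wild boar 2) for cholesterol biosynthesis, and 0.25 (Rongchang 3) to 0.64 for mitochondrially encoded genes, which quantile normalization brought to 0.050. Leaving out 1 library gave 0.0084 (Rongchang 1) to 0.18 for the stress axis and 0.091 (Rongchang 2) to 0.21 for immediate-early genes, which library weights brought to −0.0012. The acute-phase list likewise ran from 0.0049 (Rongchang 2) to 0.20, and the Toll-like receptor list from 0.0094 (Rongchang 2) to 0.11.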

Other observations

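Other brain genes are given as values, and none passed over all genes (0 in limma, adjusted p from 0.766 to 0.869). TTR was chosen for 1 high library and the others for the smallest p in their list; 3 had an unadjusted p under 0.05. CRYM, which encodes a thyroid hormone-binding protein, stood at 156 ± 34.2 FPKM in Rongchang and 93.9 ± 15.2 in wild boar (n = 3 per breed, log2 fold change −0.72). CARTPT, the precursor of the CART neuropeptide, stood at 29.5 ± 10.1 and 16.3 ± 0.883 (−0.77) and fell when adjusted over its list alone (adjusted p = 0.0451). The 2 striatal neuropeptide precursors with the smallest p lay in opposite directions: TAC1, the precursor of substance P, stood at 6.20 ± 0.993 and 2.81 ± 1.53 (−0.98), and PENK was higher as given above. TTR, the transthyretin of choroid plexus, was at 34.2 FPKM in wild boar 3 and between 0.12 and 3.01 in the other 5 libraries (1.07). KIT, a receptor of neural crest cells that lay first in that list, stood at 5.88 ± 0.0748 and 4.94 ± 0.236 (−0.21).

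Besides ENSSSCG00000008843, 3 genes without a symbol were listed at 0 in all libraries of 1 breed and at 1 FPKM or more in all of the other. ENSSSCG00000020580 was at 5.36, 28.5 and 12.2 FPKM and ENSSSCG00000029152 at 6.60, 25.9 and 7.58 in the Rongchang libraries, and both were listed at 0 in wild boar. ENSSSCG00000030287 was at 1.54, 1.51 and 1.05 in wild boar and listed at 0 in Rongchang. Another split of the 6 libraries also gave 4 such genes. Of 82 nuclear oxidative phosphorylation, ribosomal and glycolysis genes, 0 were listed at 0 in any library.

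All tests below were chosen after the results were seen except 3, on the cell mix of same-numbered libraries, on mitochondrial transcripts and on a single library behind the interferon score. With 3 animals per breed there are 10 splits of the libraries, which cannot give a share under 0.1. The breeds gave 1 gene and another split up to 4, and 7 of the 10 splits gave as many. They gave 1 immune list against up to 6 (9 of 10 splits gave as many), 1 cell type or region list against up to 8 (9 of 10), 3 other lists against up to 5 (7 of 10), and 0 list members against 0 (10 of 10; limma, 40 at an unadjusted p under 0.05 between the breeds). The numbers were taken to pair the libraries, from the data alone. On that reading, the breed split compares best with the 3 other splits that part all pairs. Those gave 94 to 186 genes at an unadjusted p under 0.05 against 789, and 0 to 6 lists against 5. After median scaling they gave 126 to 178 genes against 494, where evenly spread p-values would give 658. Each side of those 3 splits holds both breeds, so a breed difference would widen their spread. Their counts are therefore no clean measure of chance. Of the 5 lists, 4 also passed in at least 1 of those 3 splits, with a lowest adjusted p of 1.33e-09 for interferon-stimulated, 0.000291 for mitochondrially encoded, 0.00114 for endothelial and 0.00957 for immediate-early genes. The cholesterol list stood at 0.178 to 0.363 there, but lists chosen because they passed between the breeds will tend to be weaker elsewhere. The 6 splits that keep 2 pairs together gave 7 to 16 lists and 197 to 1979 genes, and in these the cholesterol list reached adjusted p as low as 2.60e-04. Counts of 1037 to 1979 genes came only where both libraries numbered 2 lay on the same side. Where these were parted and the other pairs kept, the splits gave 450 and 197 genes, below the 789 of the breeds, and 10 and 11 lists. The high gene counts thus followed the libraries numbered 2, and do not show a structure that follows every number.

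Libraries of the same number deviated together in both breeds. Those numbered 2 had low ribosomal protein scores (−0.66 in Rongchang and −0.74 in wild boar, after median scaling) and high glutamatergic scores (0.26 and 0.30). Joint preparation or sequencing of each number is a candidate explanation: for 6 of 6 libraries, low values stood in a fixed ratio most often with the library of the same number (5.34% to 23.5% of ratios for same-numbered pairs, 3.20% to 10.2% for others), but so did higher values, in 4 ranges from 0.15 to 100 FPKM, for 4 to 5 of 6, so likeness of expression from any cause gives much the same ranking and this stays open. A like mix of cell types within each number was tested by the share of within-breed variance that goes with the number, whose median over 14 marker lists was 74.0% against 74.7% ± 9.29 for 1000 sets of random lists, the 46.8th percentile. This met the bound written in advance against a like mix, the 50th percentile, but by less than the spread, a comparison added after the value was seen. Single lists ran from 14.9% (cerebellum) to 98.2% (glutamatergic). A cell mix that follows the number could raise the share of random lists too. The test therefore could not decide, and the explanation stays open.

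The median gene lay lower in wild boar, with library medians of 6.40 to 7.02 FPKM against 7.16 to 7.72 (exact permutation p = 0.1, the smallest possible). A larger share of mitochondrial transcripts in wild boar may push the other genes down. After the 13 mitochondrially encoded genes were left out and totals equalised, the median fold change was −0.11, where −0.13 had been found with them. That met the bound of −0.10 set in advance against this explanation, and leaving these genes out removed little of the shift in these libraries. The bound was passed by less than the standard error of 0.0777 between libraries, a comparison also added after the value was seen. That error bears on whether the remaining shift differs from 0, which stays open. Median log2 values stayed lower in wild boar within each number (2.85, 3.04 and 2.92 against 3.11, 3.12 and 2.96). Wild boar 2 then lay above Rongchang 3, so the breeds were no longer fully apart. A breed difference and the scaling of the deposited values were not tested as causes.

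The interferon list was lower in wild boar in camera, but not with an estimated correlation (adjusted p = 0.715) or in fry (0.485), with scores of 0.36, −0.25 and 0.18 in Rongchang and −0.03, −0.12 and −0.12 in wild boar relative to each library's median gene. Fewer microglia in the wild boar tissue might lower it, but the microglia score exceeded the interferon score by 0.31 ± 0.262 (SE) in the breed difference, which decides neither way. A single library could carry the difference: it went from −0.19 (SE 0.184) to −0.054 (SE 0.217) without Rongchang 1 and to −0.36 without Rongchang 2, which leaves this open. A breed difference in the interferon response was not tested against these.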
